A study of Arabidopsis thaliana with 6 samples.

How the data were processed

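RNA was sequenced from Arabidopsis thaliana pollen of the Col accession. Per the labels, pollen was collected from plants whose genotype is written PAPS1 pLat52::RFP / paps1-3, meaning that a red fluorescent protein driven by a pollen promoter is listed with the normal PAPS1 allele and the other chromosome carries the paps1-3 allele. Grains were separated by flow sorting on that fluorescence, which divides pollen of the same plants into a mutant and a wild-type fraction. As the genotype is written, paps1-3 grains would be the non-fluorescent ones, but the labels do not spell this out, and sort gates and purities are not given in the sources used here. Total RNA was made into libraries with the Ovation RNA-seq system v2, an amplification kit that does not mark strand, and read as pairs of 101 and 99 bases. There were 3 libraries per genotype, lettered A to C in each. Nothing in the labels says that the letters mark separate plants or growth batches, so the p-values measure only the spread between these libraries, which may be technical.

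The deposited values are raw counts of reads per gene, made by the authors with TopHat2 for alignment and HTSeq for counting on the TAIR10 build, per the submitters' processing notes; versions, options and the gene annotation are not given in the sources used here. Each library has its own table of 33602 genes, followed by summary categories that name no gene and were left out of library sizes and tests. Reads without a feature made up 1.52% ± 0.33 of all genes and categories together in paps1-3 and 1.24% ± 0.09 in wild type (mean ± SD, n = 3 each). Ambiguous reads made up 2.46% ± 0.17 and 2.34% ± 0.10, and the categories for low quality and for unaligned reads held 0 in every library. Reads placed at several positions have a category of their own, so near-identical gene copies lose reads or share them. Values of BIP1 and BIP2, the actins, histone H4 genes, RBCS genes, VGD1 and VGDH1, and tandem polygalacturonase genes are uncertain for that reason. Genes with overlapping or antisense partners are uncertain because the libraries do not mark strand and reads over both genes fall among the ambiguous ones.

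Gene names, gene classes and product names were taken from the RefSeq annotation of assembly TAIR10.1. Because that is a later release than the authors' build, no coordinates are printed. Of the identifiers, 32835 matched and 767 did not, of which 488 were not organelle genes; unmatched genes keep their identifiers. The annotation has no class for transposable element genes. Its class of untranscribed pseudogenes holds 3911 loci, of which 29 are described as transposons in their notes, and both sets were used in its place.

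Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, TMM scaling factors, genotype as the only term and genes kept by filterByExpr (minimum count 10, minimum total 15), which left 14273 genes. Calls used Benjamini-Hochberg adjusted p below 0.05. Errors of log2 fold changes are standard errors from the same test, and levels are CPM on the TMM-scaled library size, as mean ± SD of 3 libraries. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 25 lists that had at least 3 tested members. The 22 lists, the tests and the alternatives were fixed before the data were examined; 5 classes from the annotation joined them as planned. Adjusted over the list alone, member counts were the same as over all genes tested except in the list of DNA methylation maintenance, demethylation and silencing (8 instead of 7 higher) and the photosynthesis list (4 instead of 3 lower). The 18 shares of counts were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

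Named genes followed a rule fixed at the same time: the poly(A) polymerases; the 12 largest increases and 12 largest decreases among called genes with an average log2 CPM of at least 3 and no overlap between groups; in each list up to 4 called members with the smallest p, or the 2 most abundant where none was called; and 4 transposon loci with the smallest p. Genes named outside the rule are marked as chosen after their values were seen, and 1 gene among the largest decreases is not reported here.

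On simulated counts for 9855 genes, drawn from the wild-type means, the real library sizes and the estimated dispersions, with 100 genes changed 2-fold and 100 changed 4-fold, the edgeR step for paps1-3 against wild type recovered 73% of the 2-fold and 97% of the 4-fold changes, all with the right sign, and made 9 false calls (5.03% of calls). Changes were simulated in few genes and in equal numbers up and down, whereas 10310 of 14273 genes were called in the real data. The simulation therefore did not hold the shift in composition seen there, and its error rate and signs do not carry over. Library pairs within a group differed by 15.3 to 29.7 times the chi-square expected from counting noise, so no library was treated as a copy of another.

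Alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the letter as a block, organelle and rRNA genes left out, an adjusted p below 0.01, each library left out in turn, and for lists an estimated correlation and fry. Library totals without a scaling factor, leaving out both libraries lettered A, and thinning for gene detection were added after seeing the data. Total counts per library ranged from 19861313 to 41176647; counts of amplified reads are not independent molecules, so limits from low counts cover counting error only.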

Results

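Transcripts of pollen carrying the paps1-3 allele of the poly(A) polymerase gene PAPS1 were compared with those of wild-type pollen sorted from the same kind of plants. PAPS1 encodes a canonical nuclear poly(A) polymerase, which adds poly(A) tails to messenger RNA precursors. Per the series title, the study asks how PAPS1 relates to RNA-directed DNA methylation. The 3 paps1-3 libraries held 36697737 (A), 41176647 (B) and 19861313 (C) gene counts, and the 3 wild-type libraries 31909683 (A), 32755496 (B) and 37685541 (C).

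PAPS1 (AT1G17980) itself was near the limit of detection in both groups and lower in paps1-3. It had 18, 9 and 3 counts in paps1-3 libraries A, B and C and 32, 25 and 20 in the wild-type libraries, or 0.181 ± 0.099 against 1.17 ± 0.33 CPM (n = 3 each). The log2 fold change was −2.61 ± 0.57 (SE, adjusted p = 0.000273 by edgeR), and by library totals −1.35 (adjusted p = 0.0465), and its CPM was lower in each paps1-3 library than in any wild-type library. The paralogs were more abundant in pollen. PAPS2 (AT2G25850) had a log2 fold change of −2.24 ± 0.18, the cytosolic PAPS3 (AT3G06560) of −1.57 ± 0.14 and the most abundant, PAPS4 (AT4G32850), of −1.36 ± 0.13, from 114 ± 5.5 CPM in wild type to 44.5 ± 2.4 in paps1-3. All 4 polymerase genes were lower (camera adjusted p = 0.0140; adjusted p = 0.237 with an estimated correlation). The list missed the threshold with a filter of 1 CPM in 3 libraries (adjusted p = 0.0505) and by library totals (adjusted p = 0.0587), where PAPS4 did not pass either (−0.12, adjusted p = 0.335).

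More genes were detected in paps1-3 pollen. At least 1 count was found for 27461 ± 2878 genes in paps1-3 and 18287 ± 1400 in wild type (n = 3 each), and after thinning to the smallest library for 26230 ± 2457 and 16620 ± 1210, with no overlap between groups (exact permutation p = 0.1, the smallest possible). There were 2861 genes with 0 counts in all wild-type libraries and a count in all paps1-3 libraries, against 8 in the reverse direction; a count of 0 allows up to 3 counts.

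**Figure D1:**
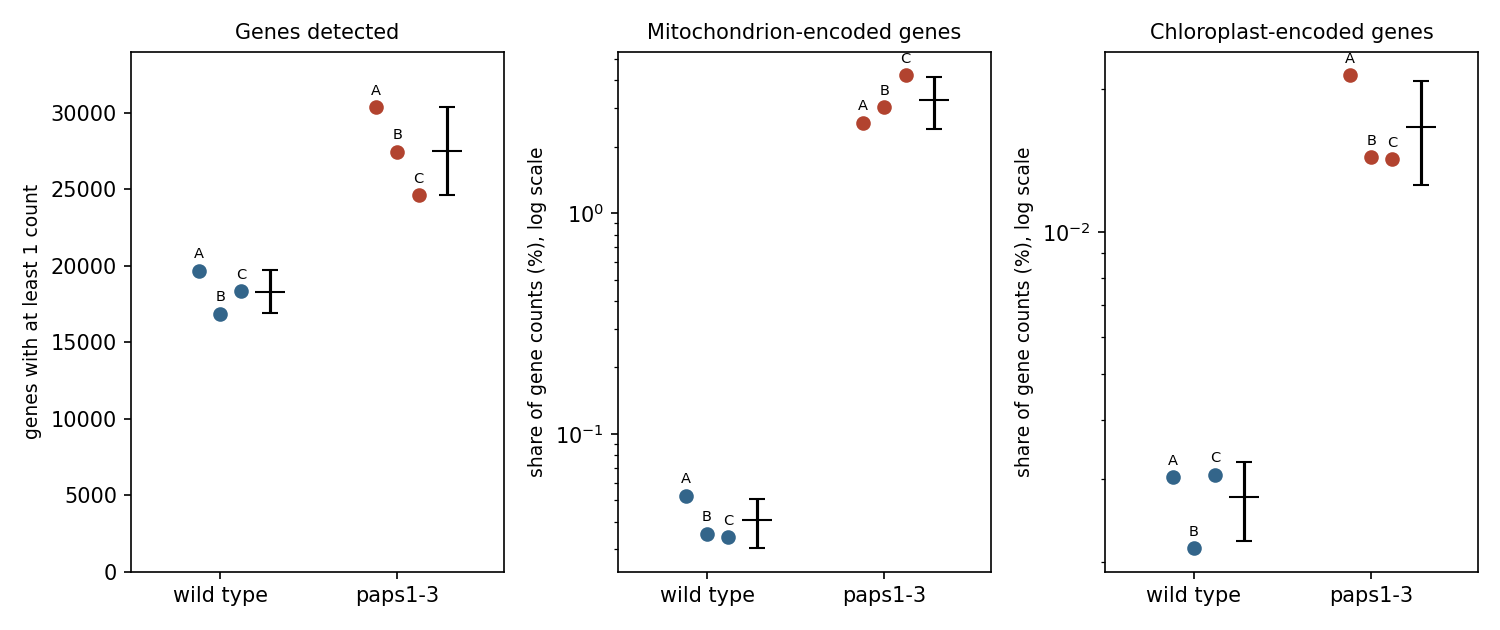
Genes with at least 1 count (left, linear axis) and the share of gene counts, in percent on log axes, from mitochondrion-encoded (middle) and chloroplast-encoded genes (right). Points are libraries with their letters, and bars are mean ± SD of 3 libraries. Every paps1-3 library lies above every wild-type library in each panel.

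Of 14273 genes tested, edgeR called 10310 changed: 6037 higher and 4273 lower in paps1-3. More than 4-fold changes were made by 3632 of the higher and 1037 of the lower genes. Libraries did not overlap between groups for 5806 of the higher and 4172 of the lower genes. Chance alone gives this in 10% of unchanged genes. These genes were already called from the same libraries, so little overlap was bound to follow and adds no separate support. The split into higher and lower depended on scaling, because the TMM factors were 1.47 to 1.68 in paps1-3 and 0.61 to 0.67 in wild type. By library totals alone 10031 genes were higher and 1385 lower, so that 87.9% of calls were increases instead of 58.6%. The median log2 fold change of tested genes moved from 0.37 to 1.63, and the median shift per gene was 1.25. The 6037 higher genes and 1385 of the lower ones kept their direction under both scalings, and 933 were called in opposite directions. The 1000 most abundant genes had a median log2 fold change of −1.32 by TMM and −0.07 by totals. Decreases between 0 and about −1.25 are therefore decreases only relative to the TMM reference.

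**Figure D2:**
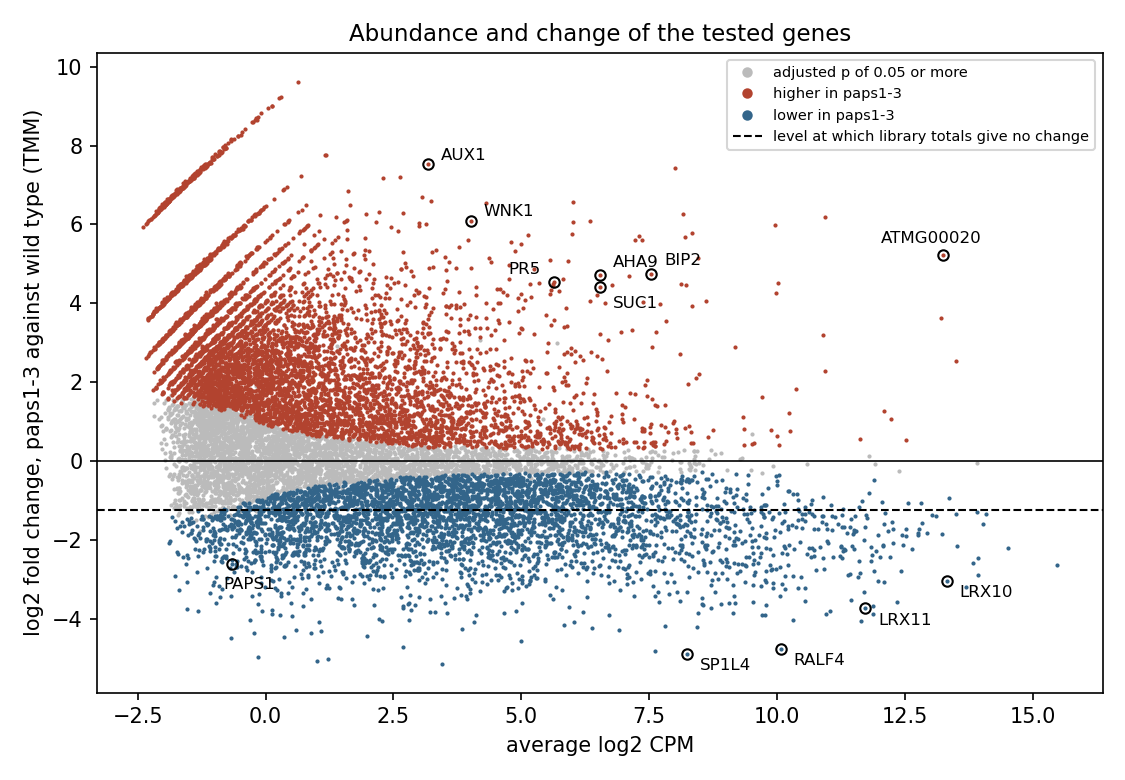
Log2 fold change (paps1-3 against wild type, TMM) against average log2 CPM for the 14273 tested genes, coloured by call at adjusted p 0.05. The dashed line marks −1.25, where library totals give no change. Most abundant genes lie below 0 and the increases are most numerous at low abundance, where diagonal bands hold genes with few or 0 wild-type counts whose fitted values depend on the prior count; some genes of the text are circled.

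Among genes of at least moderate abundance, the largest increases spanned low and high levels. AUX1 (AT2G38120), an auxin influx carrier, had a log2 fold change of 7.53 ± 0.31, with 1007, 977 and 577 counts in paps1-3 A, B and C against 3, 1 and 2. Genes of late embryogenesis abundant proteins, which accompany desiccation, followed with AT5G53820 (7.43 ± 0.19) and AT4G13230 (6.27 ± 0.18), and AT1G47980, described as a desiccation-like protein, reached 6.56. BBX9, a B-box zinc finger gene (AT4G15250), rose by 6.58, the kinase gene WNK1 (AT3G04910) by 6.10, and LCR5 (AT2G28355), which encodes a small cysteine-rich protein, by 6.06. The most abundant of the increases was AT3G28770, a gene of unknown function with a DUF1216 domain, at 3872 ± 1480 against 53.4 ± 14.7 CPM (6.18 ± 0.38). The others were AT2G15555 (a non-coding RNA, 6.69), AT1G68250 (6.61), the esterase gene AT5G42170 (6.08) and the kinase gene AT1G72760, from 0.255 ± 0.059 to 16.7 ± 0.9 CPM. All 12 were called under both scalings.

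The largest decreases included abundant pollen genes, and all 12 were called under both scalings. RALF4 (AT1G28270), which encodes a secreted peptide that keeps growing pollen tubes intact, fell from 2077 ± 259 to 77.0 ± 6.3 CPM (log2 fold change −4.75 ± 0.15), and the related RALFL26 (AT3G25170) changed by −4.18 ± 0.14. SP1L4 (AT5G15600), a relative of the microtubule protein SPIRAL1, changed by −4.88 ± 0.15, from a wild-type level of 589 ± 71 CPM. CKS2 (AT2G27970), a subunit of cyclin-dependent kinases, changed by −4.09 ± 0.17. AT5G46150, of the CDC50 family, was at −4.27, AT1G72340 at −4.23 and the glycosyltransferase gene AT1G28710 at −4.16. The uncharacterised AT4G14810, AT3G26934 and AT5G08240 were at −5.13, −4.80 and −4.57, and the non-coding RNA AT3G14185 at −4.26.

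Genes of pollen tube growth and signalling were lower as a group. Of 30 tested, 22 fell, 5 rose and 3 did not pass (camera adjusted p = 5.91e-08; adjusted p = 0.427 with an estimated correlation). By library totals 13 fell and 12 rose, and the 13 were among the 22. Besides RALF4, the cell wall proteins LRX11 (AT4G33970) and LRX10 (AT2G15880) fell, with log2 fold changes of −3.72 ± 0.15 and −3.03 ± 0.14 and wild-type levels of 6323 ± 666 and 18271 ± 2208 CPM. The proton pump gene AHA9 (AT1G80660) went the other way, from 6.81 ± 0.12 to 179 ± 23 CPM (4.71 ± 0.15). Pectin-modifying enzymes of pollen also divided: 9 of 14 fell and 4 rose (adjusted p = 0.00929; adjusted p = 0.676 with an estimated correlation). By totals 5 fell and 6 rose, and the list no longer passed (camera adjusted p = 0.268). With the letter as a block it also missed the threshold (camera adjusted p = 0.0527). The pectate lyase genes AT59 (AT1G14420) and AT3G01270 changed by −3.87 ± 0.16 and −3.19 ± 0.15 and the polygalacturonase gene AT3G07820 by −2.58 ± 0.14, while its neighbour AT3G07830 rose by 3.93 ± 0.15.

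Sperm cell genes showed decreases alone: 12 of 15 fell and 3 did not pass (camera adjusted p = 5.12e-05; adjusted p = 0.237 with an estimated correlation). By totals 5 fell and 3 rose. MAPKKK20 (AT3G50310) changed by −3.57 ± 0.16 and PCR11 (AT1G68610) by −2.85 ± 0.16. TET12 (AT5G23030) changed by −2.82 ± 0.24 and GEX1 (AT5G55490), which acts in gametes, by −1.75 ± 0.14, and these 4 also fell by totals.

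Other pollen lists moved in both directions and did not pass as groups. Of 9 cytoskeleton genes 3 rose and 3 fell, and 8 rose and 1 fell by totals (adjusted p = 0.781, direction of the test down, median log2 fold change 0.11, mean −0.10). ACT12 (AT3G46520) fell by 2.17 on the log2 scale, the profilin genes PRF4 (AT4G29340) and PRF5 (AT2G19770) rose by 1.03 and 0.89, and ACT11 (AT3G12110) was at −0.77 by TMM and 0.47 by totals. Of 12 pollen transcription factors 4 rose and 5 fell, and 7 rose and 4 fell by totals. The camera adjusted p was 0.150, and 0.0295 without a filter on low counts (direction of the test down, median 0.03, mean −0.40). BZIP18 (AT2G40620) was at −2.30, MYB97 (AT4G26930) at −2.13, AGL104 (AT1G22130) at −1.85 and WRKY2 (AT5G56270) at −1.77, all lower by totals as well. All 6 sugar and water transport genes were called, 4 higher and 2 lower (adjusted p = 0.664). The sucrose symporter gene SUC1 (AT1G71880) rose by 4.42 ± 0.18 and the tonoplast water channel TIP1;3 (AT4G01470) by 2.71, while the hexose transporter STP11 (AT5G23270) changed by −3.21 ± 0.14 and TIP5;1 (AT3G47440) by −2.21.

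In RNA-directed DNA methylation, 13 of 20 tested genes rose and 4 fell, which did not set the list apart from other genes (camera adjusted p = 0.338; 16 rose and 1 fell by totals). The de novo methyltransferase DRM2 (AT5G14620) rose by 4.80 ± 0.46, from 0.108 ± 0.074 to 3.06 ± 0.71 CPM, RDM1 (AT3G22680) by 3.85 ± 0.54 and the effector AGO4 (AT2G27040) by 2.14 ± 0.29. AGO9 (AT5G21150), its more abundant relative in wild-type pollen at 23.0 ± 0.5 CPM, changed by −2.10 ± 0.15. Of 11 tested genes of the post-transcriptional small RNA pathway, 9 rose and 0 fell, and by totals all 11 rose. The list did not pass (camera adjusted p = 0.0917, by totals 0.338), but did without a filter on low counts (0.0172) and just so without paps1-3 A. DCL1 (AT1G01040), the microRNA dicer, rose by 1.80 ± 0.18 and AGO1 (AT1G48410) by 2.56 ± 0.58. AGO2 (AT1G31280) had 141, 163 and 91 counts in paps1-3 against 0, 0 and 2, and HYL1 (AT1G09700) had 79, 42 and 13 against 1 in each wild-type library.

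Genes that maintain, remove or read DNA methylation divided, with 7 of 17 higher and 8 lower (adjusted p = 0.501, direction of the test down, median −0.16, mean 0.57; 11 and 3 by totals). The CG maintenance methyltransferase MET1 (AT5G49160) changed by −2.57 ± 0.15, the chromatin remodeller DDM1 (AT5G66750) by −2.30 ± 0.14 and VIM1 (AT1G57820) by −2.10 ± 0.20, all lower under both scalings. VIM3 (AT5G39550), a relative of VIM1 chosen after its values were seen, was at −0.70 ± 0.19 by TMM and 0.55 by totals and was called in both. The histone methyltransferase gene SUVH5 (AT2G35160) was at −1.55 by TMM and −0.30 by totals, where it did not pass. The list of loci taken as silenced by methylation had 3 tested members (camera adjusted p = 0.781). Of these, PHE1 (AT1G65330) was called, with 55, 48 and 12 counts against 0, 1 and 1. Methylation was not measured, so the rise of PHE1 does not show a loss of silencing by methylation. QQS (AT3G30720), chosen after its values were seen, was at 0.18 ± 0.35 by TMM and was called by totals (1.42, adjusted p = 0.00214). FWA (AT4G25530), the remaining locus and also chosen after its values were seen, was called under neither scaling (−0.51 by TMM, 0.72 by totals). Transposable element genes have no class in the annotation, so loci described as transposons and the untranscribed pseudogene class stood in for them. How many of that class are transposable element genes was not determined. The loci described as transposons were few and moved both ways. Of 11 tested loci described as transposons, 4 rose and 2 fell (adjusted p = 0.787), and by totals 7 rose and 1 fell. SADHU3-1 (AT3G44042) and SADHU5-1 (AT4G01525) rose by 1.24 ± 0.15 and 1.67 ± 0.21, while SADHU1-1 (AT2G10410) changed by −1.71 ± 0.17 and SADHU1-3 (AT5G28626) by −1.34 ± 0.26, the last not past the threshold by totals (−0.11). In the untranscribed pseudogene class 192 of 357 tested loci rose and 59 fell (adjusted p = 0.0567; 0.00192 to 0.0446 when any library except paps1-3 A was left out, 0.124 without that). By totals 283 rose and 16 fell, and the class was far from the threshold (adjusted p = 0.915). Its share of counts was 0.301% ± 0.070 against 0.145% ± 0.015 (exact permutation p = 0.1). Transcribed pseudogenes had 49 of 111 higher and 34 lower (adjusted p = 0.678), and 64 higher and 14 lower by totals (adjusted p = 0.643, direction of the test then down).

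The list of mRNA 3'-end processing factors was lower relative to other genes, with 11 of 19 falling and 6 rising (camera adjusted p = 0.0257, and 0.237 with an estimated correlation). Its median log2 fold change was −0.92 and its mean −0.02. By totals 7 fell and 9 rose, with a median of 0.33, and the list no longer passed (camera adjusted p = 0.0587). With the letter as a block it did not pass either (camera adjusted p = 0.0569). PCFS4 (AT4G04885) changed by −3.68 ± 0.21 and PCFS1 (AT1G66500) by −1.97 ± 0.13, both related to a yeast cleavage factor, the flowering regulator FPA (AT2G43410) by −1.96 ± 0.13 and FIPS5 (AT5G58040) by −1.75 ± 0.12, all lower by totals too. Poly(A)-binding proteins did not pass as a list (5 of 8 higher, 2 lower, adjusted p = 0.587; 6 and 1 by totals). PAB5 (AT1G71770), at 882 ± 49 CPM in wild type, changed by −2.66 ± 0.13 and PAB2 (AT4G34110) by −1.27 ± 0.14, which was −0.03 and not past the threshold by totals. PAB3 (AT1G22760) rose by 2.17 and PAB4 (AT2G23350) by 2.37.

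Genes of the unfolded protein response, which act on protein folding in the endoplasmic reticulum, rose. Of 13 tested, 10 were higher and 0 lower (camera adjusted p = 2.32e-08; adjusted p = 0.237 with an estimated correlation), and by totals all 13 were higher. SHD (AT4G24190), the chaperone of the HSP90 family in that compartment, rose by 5.05 ± 0.18, the HSP70 chaperone BIP2 (AT5G42020) by 4.75 ± 0.17, from 13.4 ± 2.2 to 360 ± 75 CPM, calnexin CNX1 (AT5G61790) by 4.28 ± 0.20 and the disulfide isomerase PDIL1-1 (AT1G21750) by 3.62 ± 0.18. Cytosolic ribosomal protein genes rose too, 27 of 31 being higher and 3 lower (adjusted p = 3.45e-06; adjusted p = 0.538 with an estimated correlation). RPS3A (AT2G31610) rose by 5.82 ± 0.30, RPS8A (AT5G20290) by 5.31 ± 0.30 and RPS15AA (AT1G07770) by 4.79 ± 0.34, while RPL10C (AT1G66580), at 237 ± 36 CPM in wild type, changed by −2.21 ± 0.15. By totals 29 rose and RPL10C alone fell.

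**Figure D3:**
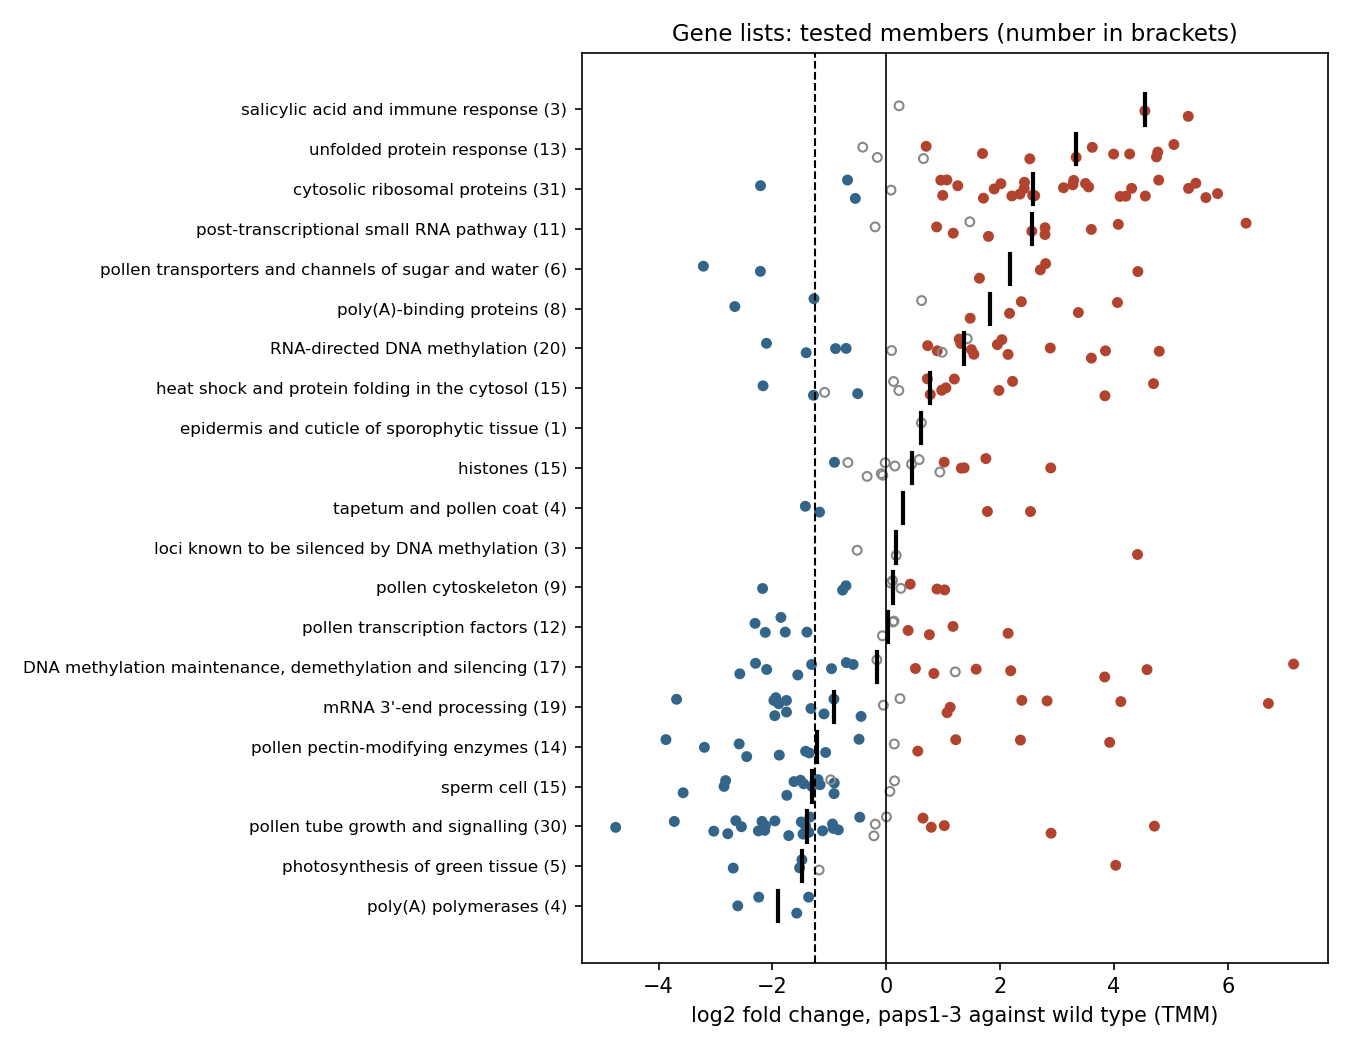
Log2 fold change (paps1-3 against wild type, TMM) of each tested member of the gene lists, ordered by median. Filled points were called at adjusted p 0.05 (red higher, blue lower), open points were not, and black bars are list medians. The dashed line at −1.25 marks no change by library totals; unfolded protein response genes lie mostly right of 0 and pollen tube genes mostly left of it.

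Genes of the list for heat shock and protein folding were mixed (camera adjusted p = 0.678). By TMM 9 of 15 were higher and 3 lower, and by totals 12 were higher and 0 lower. HSP22 (AT4G10250) rose by 3.84 ± 0.57, HSP18.2 (AT5G59720) by 2.22 ± 0.46 and HSP101 (AT1G74310) by 1.05 ± 0.19. HSP23.6 (AT4G25200), placed in mitochondria by its product name, had 42, 27 and 8 counts against 0, 1 and 0. Of 15 histone genes 5 rose and 1 fell by TMM, and 12 rose and 0 fell by totals (adjusted p = 0.740): HTR4 (AT4G40030) was at 1.02, HTB9 (AT3G45980) at 2.89, and the H4 genes AT1G07660 and AT5G59690 at 1.32 and −0.91, the last 0.32 by totals. In the salicylic acid and immune list 3 of 19 genes had enough counts, of which 2 rose, and all 3 by totals (camera adjusted p = 0.0433; adjusted p = 0.408 with an estimated correlation). PR5 (AT1G75040), a pathogenesis-related protein, rose by 4.54 ± 0.18, from 4.09 ± 0.48 to 95.6 ± 20.6 CPM, and the regulator SARD1 (AT1G73805) had 40, 41 and 26 counts against 1, 0 and 0. That list call was lost by totals (camera adjusted p = 0.0587), without a filter on low counts (0.248), with the letter as a block (0.189) and when any library was left out (0.066 to 0.165). No SAUR gene of the 18 in that auxin list had enough counts to test.

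RNA encoded in the mitochondria took 3.27% ± 0.85 of counts in paps1-3 and 0.0405% ± 0.0102 in wild type, 80.6 times as much (n = 3 each, exact permutation p = 0.1, adjusted over the shares 0.164). Most of it came from ATMG00020, a mitochondrial ribosomal RNA gene, and without it the shares were 0.376% ± 0.091 and 0.00743% ± 0.00155. All 26 tested mitochondrial genes rose under both scalings (camera adjusted p = 1.79e-15; adjusted p = 0.237 with an estimated correlation). Of 44 chloroplast-encoded genes 36 rose and 0 fell, and by totals all 44 rose (camera adjusted p = 0.00276, by totals 0.250; adjusted p = 0.676 with an estimated correlation), their share being 0.0167% ± 0.0041 against 0.00274% ± 0.00052. Nuclear small nuclear RNA loci also took more counts, 0.0114% ± 0.0013 against 0.000410% ± 0.000047 (exact permutation p = 0.1). Counts on nuclear ribosomal RNA loci did not differ beyond the spread (0.0741% ± 0.0268 against 0.0690% ± 0.0156, exact permutation p = 0.8). They leave out reads placed at several positions, so they do not measure ribosomal RNA of near-identical gene copies. The share of the 10 most abundant genes did not differ beyond the spread either (19.5% ± 1.2 against 20.17% ± 0.30, exact permutation p = 0.4).

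Markers of other tissues took small shares of counts that were higher in paps1-3 for the tapetum and epidermis lists. These are shares of library totals, by which the median log2 fold change of all tested genes was 1.63. A higher share alone therefore does not set such markers apart from other genes. The 22 tapetum and pollen coat genes took 0.000784% ± 0.000551 of counts in paps1-3 (0.000468% without library A) and 0.000237% ± 0.0000092 in wild type, and the 8 epidermis genes 0.000210% ± 0.000112 and 0.0000245% ± 0.0000168, both without overlap between groups. The 20 photosynthesis genes took 0.000789% ± 0.000174 and 0.000580% ± 0.0000406, with overlap. Only 4 of 22 tapetum and pollen coat genes could be tested, 2 higher and 2 lower, and by totals 2 higher and 0 lower (adjusted p = 0.991): LAP6 (AT1G02050) at 2.54 ± 0.65 and MYB80 (AT5G56110) at 1.78 ± 0.72, and AMS (AT2G16910) at −1.17 ± 0.38 and MS2 (AT3G11980) at −1.42 ± 0.62. By totals AMS was at 0.08 and MS2 at −0.13, neither past the threshold. Single libraries decided several of these calls: AMS did not pass without wild type B (−1.01), MYB80 without paps1-3 B (1.26), wild type A (1.16) or wild type B (1.73), and MS2 when any library except paps1-3 A was left out (−0.98 to −1.60). Of 20 photosynthesis genes 5 could be tested, 1 higher and 3 lower, and by totals 1 higher and 1 lower (adjusted p = 0.587). RBCS3B (AT5G38410), RBCS2B (AT5G38420) and LHCB3 (AT5G54270) were at −1.48, −1.52 and −2.69, of which only LHCB3 was lower by totals. RBCS2B did not pass when any library except paps1-3 A was left out (−1.38 to −1.81), and without paps1-3 A it had too few counts to be tested. PSBO1 (AT5G66570) had 23, 38 and 19 counts against 0, 0 and 2. The epidermis list had 1 testable gene of 8, FDH (AT2G26250), at 0.62 ± 0.63 by TMM (adjusted p = 0.389), which was higher by totals (1.85, adjusted p = 0.0113). The genotypes separated on the first principal component (85.4% of variance), and the libraries lettered A of both groups stood apart from B and C on the next (5.33%).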

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

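The tests in this part were chosen after the results were seen. Reads aligned to more than 1 place lie outside the gene counts that were compared. They made up 9.84% ± 1.87 of all genes and categories together in paps1-3 and 5.59% ± 0.48 in wild type, higher in all 3 paps1-3 libraries than in any wild-type library (n = 3 each, exact permutation p = 0.1, adjusted over the 18 shares 0.164). No explanation was tested for them.

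For the larger number of genes detected in paps1-3, depth is argued against by the thinned libraries, in which the difference was 9610 genes against 9174 as deposited. RNA of green tissue is argued against as the whole source by its abundant transcripts. The 20 photosynthesis genes took 0.000789% of paps1-3 counts and 0.000580% of wild-type counts. In paps1-3 the 8480 genes silent in wild type took 0.103% ± 0.062 (0.0667% without paps1-3 A). The photosynthesis share may be too low, because near-identical RBCS copies lose reads placed at several positions. Chloroplast-encoded genes took 0.0167% in paps1-3 against 0.00274%, also less than the silent genes. Green tissue as a part of the source stays open. Tapetum and epidermis cannot be told apart, because their markers were higher in every paps1-3 library (0.000784% against 0.000237%, or 0.000468% without paps1-3 A, for tapetum and 0.000210% against 0.0000245% for epidermis) and no profile of either tissue was measured. Their markers too took less than the genes silent in wild type. Another rule was set for these tissues than for green tissue, so the different outcome comes from the rule and not from lower values. Genomic DNA is argued against as the source of the summed gain of the genes called higher. Together they gained 24.6 percentage points of counts, while reads without a feature rose by 0.388 points (24.8 and 0.178 without paps1-3 A). Here those reads are a share of gene counts plus reads without a feature (1.73% in paps1-3 and 1.35% in wild type). The genes were picked as higher in the same libraries, and abundant ones weigh most. Called genes with few counts therefore stay open. For the genes silent in wild type, genomic DNA cannot be told apart. On the same base, reads without a feature rose by 0.806, 0.0486 and 0.308 points in paps1-3 A, B and C. In B the rise was less than the 0.0711% these genes took there. A change with genotype was not tested separately from the sort.

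The mitochondrial share was weighed against 2 technical explanations. A single abundant gene is argued against, since without ATMG00020 the ratio between groups was still 50.6. A common factor for all RNA without poly(A) tails is argued against as the whole cause by the chloroplast-encoded genes. Between single libraries the ratio was at most 9.998 for them and at least 33.0 for mitochondrial genes without ATMG00020. Small nuclear RNA loci, at 22.1 to 35.1, overlapped the mitochondrial range. For nuclear ribosomal RNA loci the ratio was at most 1.83. Reads placed at several positions are not in these counts, so that value cannot show whether ribosomal RNA of near-identical gene copies rose. Copies of mitochondrial DNA in the nuclear genome, the sort and the genotype itself remain open and were not tested.

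Lower abundant pollen transcripts beside higher ribosomal, chaperone and silent genes may reflect a mixture or another developmental stage of the sorted grains. Dilution of mature pollen RNA by other material cannot be told apart, because the profile of that material was not measured: of the 100 genes most abundant in wild type 10 rose and 75 fell by library totals, and the largest fall among them would need at least 85.6% of paps1-3 counts from elsewhere. Pollen at a dividing stage in the paps1-3 fraction was tested with 17 mitotic genes, of which CYCB1;1 is also in the sperm list and had been seen, and cannot be told apart: 7 were higher and 6 lower by TMM, 10 and 1 by totals, but their median log2 fold change lay below that of all tested genes (−0.07 against 0.37 by TMM, 1.17 against 1.63 by totals), and the list did not pass camera (p = 0.456; p = 0.467 with an estimated correlation). A younger stage that does not divide and an effect of the allele on development stay open as hypotheses.

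The 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 10310 changed genes by edgeR and the highest of the other splits 0. At an unadjusted p under 0.05 by edgeR there were 10 to 58 genes in those and 10587 in the real split. Only 1 split, the real one, gave as many. Every other split put both genotypes in each group, which widened the spread within groups. Few calls were bound to follow there, so the comparison decides nothing.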

How the results depend on the processing

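Library totals and leaving out both libraries lettered A were chosen after seeing the data. The count of changed genes stayed within 1.5 times of 10310 under every alternative run, from 7903 with a filter of 1 CPM in 3 libraries to 11416 by library totals; without both A libraries it was 9942, and with each library left out in turn 9709 to 10568. No gene was called in opposite directions except by library totals (933 genes), which gave 10031 higher and 1385 lower genes through their smaller scaling of paps1-3. By totals ACT11 turned to 0.47, AMS to 0.084 and the H4 gene AT5G59690 to 0.32, 7 other named genes no longer passed and FDH now did (1.85). PAPS1 kept its direction and call in each fit that tested it, from −2.46 to −3.10 with each library left out; it had too few counts for the 1 CPM filter. The calls of MYB80, MS2 and RBCS2B were lost in several leave-one-out fits and with DESeq2, those of MS2 and RBCS2B with upper-quartile factors, those of MYB80 and RBCS2B without a filter, MYB80 without both A libraries, RBCS2B with the replicate block and AMS without wild type B.

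Of the list calls (5 higher, 5 lower), library totals left 3 higher and 2 lower, and leaving out organelle and rRNA genes 3 higher by removing both organelle lists. An estimated correlation left 0 and 0 at adjusted p below 0.05; 5 lists then had an unadjusted p of 0.0270 to 0.0475. Fry, which asks whether a list's genes move on balance one way and compares them with no other genes, gave 11 higher and 8 lower, among these the methylation maintenance list with 7 genes higher and 8 lower. The pseudogene class passed when any library except paps1-3 A was left out (adjusted p 0.00192 to 0.0446) and with the replicate block (0.0359). The post-transcriptional small RNA list passed without paps1-3 A, with the block (0.0442) and without a filter (0.0172). The polymerase list missed the threshold with the 1 CPM filter (0.0505). The salicylic acid list was lost without a filter (0.248) and without both A libraries (0.0850), and the transcription factor list passed without a filter (0.0295). The cause of the other changes was not tested.

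The letters were not taken as pairing: deviations of same-letter libraries correlated at 0.231 (A), 0.0989 (B) and 0.0755 (C). Over these tested genes each library correlated best with its own letter. At an average log2 CPM of at least 3 the values were 0.419, 0.139 and 0.111, all over 0.1, but paps1-3 C correlated better with wild type B (0.141). With the letter as a replicate block, 10542 genes changed and 6 lists were higher and 3 lower, the lists for 3'-end processing (adjusted p 0.0569), pectin (0.0527) and salicylic acid (0.189) no longer passing. Depth limits PAPS1, the tissue markers and most genes silent in wild type, which rest on few counts.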

Other observations

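The groups and tests in this part were chosen after the data were seen. Product names of the annotation were used to form 259 families of at least 8 tested genes. Genes of late embryogenesis abundant proteins were higher in 11 of 12 cases (camera adjusted p = 1.27e-06, median log2 fold change 2.93), but a related family of hydroxyproline-rich glycoproteins had 4 of 9 higher and 1 lower (adjusted p = 0.963, direction of the test down, median 0.31). Small cysteine-rich proteins of the LCR family were higher in 10 of 14 cases and lower in 4 (adjusted p = 0.00226). The family of minichromosome maintenance proteins, several of which form the core of the replicative DNA helicase, had 7 of 8 genes lower, 4 of them also by library totals (adjusted p = 0.00249). Genes with ENTH, ANTH or VHS domains, which act in vesicle budding, were lower in 10 of 11 members of 1 family, 4 of them also by totals (adjusted p = 0.00246). The families named for ENTH and VHS (7 of 8 lower, adjusted p = 0.0975) and for ENTH, VHS and GAT (4 of 8 lower and 3 higher, adjusted p = 0.833, direction of the test down, median 0.18) did not pass. RALF-like peptide genes divided into 6 higher and 7 lower (adjusted p = 0.0121, direction of the test down, median −0.89), all 6 and 6 of the 7 also by totals. None of the families that passed did so with an estimated correlation (adjusted p = 0.904 for each).

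Of 11 genes with DUF1216 in a product name, a domain known mainly by sequence, 10 were tested by edgeR, of which 8 were higher and 1 lower by TMM and 9 higher and 0 lower by library totals. AT3G28820 had a log2 fold change of 5.99 ± 0.17, AT3G28840 of 5.69 ± 0.20, AT3G28980 of 3.64 ± 0.16 and AT3G28790 of 2.53 ± 0.15. AT3G28810 was at −1.40 ± 0.15 by TMM and −0.13 by library totals, where it did not pass (adjusted p = 0.375 by edgeR). These members were chosen after their values were seen. Near-identical copies in this family may share reads, which was not tested; in the fit by library totals the related AT3G28770 was at 7.47.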
